A study of Zea mays with 48 samples.

How the data were processed

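RNA was sequenced from poly(A)-selected, strand-marked libraries of maize leaves, per the labels' protocols. The 48 libraries fall into 12 groups of 4. In the B96 experiment, the inbred B73, the inbred B96 and their F1 were each sampled with and without spider mites (Tetranychus urticae). The B75 experiment has the same layout with the inbred B75 and its F1 with B73. The design text assigns separate B73 libraries to each experiment as its reference, and each fit of a line or F1 used the B73 libraries of its own experiment. The B73 of the other experiment entered only the gene sets, the comparison of both B73 responses, and 1 ratio of counts of genes in the closing section. Infested sections of leaf 4 on plants 22 days old carried 200 adult female mites for 24 hours, and control sections had the wax barrier without mites, per the labels' protocols. The labels call the libraries biological replicates and do not say how many plants went into each, so the p-values measure the spread between these samples.

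The deposited table holds 1 whole-number count per gene feature and library, made by the authors. Reads were aligned with STAR 2.5.3a to B73 RefGen_v4 and counted with HTSeq 0.9.1, per the submitters' processing notes. The counting options and any read filter are not given in the sources used here. All lines were counted on the B73 genome, so a level in B96, B75 or an F1 also carries any loss of reads to sequence differences from B73. The table has 46272 features and 5 summary lines for reads that were not assigned to a gene. The summary lines held a mean of 17.6% of the reads (12.7 to 28%), mostly reads with more than one alignment, and stayed out of library sizes and tests. Genes with near-identical copies lose reads to that category, so their levels are uncertain. The libraries held 9.98 to 20.9 M gene counts, with a median of 16.4 M in control and 12.4 M in infested leaves. No pair of libraries within a group looked like one library deposited more than once, since the lowest chi-square per gene over all pairs was 5.13.

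The features carry 44146 identifiers that start with Zm, 1798 that start with ENSRNA, 174 that start with GRMZM5G and 154 microRNA precursors named zma-MIR. The reference table used here names genes of a later assembly. It matched 0 of the Zm identifiers and 153 of the precursors. Positions and gene names are therefore left out, and the 26 gene lists fixed before the data were examined, among them benzoxazinoid and jasmonate biosynthesis, proteinase inhibitors and photosystem genes, gave no value because none of their members was matched. The rule for named features was fixed at the same time. Where names could not be matched, it took the 2 identifiers with the largest rise and the 2 with the largest fall among genes past the threshold with a mean of at least 5 CPM in the highest group and, where 2 groups were compared, no overlap between their libraries. The precursors in the tests were added after the data were seen, as the only features that the table names.

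Tests used R 4.3.3 and edgeR 4.0.16. Each experiment was fitted on its own with all 24 libraries, which share one estimate of the spread, as group means without covariates. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and contrasts were tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05 over all genes of the fit. This left 22569 genes in the B96 experiment, 22572 in the B75 experiment and 21017 in the fit of the B73 libraries alone. A gene past that threshold is said to have changed, risen or fallen. CPM are counts per M counts of the TMM-scaled library size, and values are given as mean ± SD of 4 libraries. Log2 fold changes are given ± SE. Where a group had no count, its level was set to 3 counts over the 4 libraries of the group and a fold between 2 groups is given as at least that large, for counting error only. A difference of responses or from the mid-parent is a fitted value, which depends on the prior count and is no bound where a group in it has no or few counts. A mite response is infested minus control, a difference of responses is the interaction of line and infestation, and the mid-parent is the mean of both parents on the log2 scale. The contrasts, the alternatives and the mid-parent scale were fixed before the data were examined.

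In place of the unmatched lists, mite-induced and mite-repressed gene sets were formed after the data were seen. A set holds the genes that changed at least 2-fold with mites in the B73 libraries of the other experiment, so that no library of a test defined its own set, and the sets are biased towards genes that respond in B73. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 2 sets and all contrasts of an experiment. Camera asks whether a set differs from the other genes, and fry whether its members changed, without regard to other genes. Set scores are the mean log2 CPM of the members minus that of the B73 control libraries, compared by two-sided exact permutation tests of 4 against 4 libraries, adjusted over 28 comparisons. No such test can give a p under 0.0286 here, which is 0.0534 after adjustment. Silent genes were those with under 3 counts over the 8 libraries of one parent and a mean of at least 5 CPM over the 8 of the other. The comparisons of the F1 response with that of each parent, the genes shared by all responses, the silent genes, the position of the F1 between its parents and the order of identifiers were also chosen after the data were seen.

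The steps were tested on simulated counts drawn from the B73 control means and the estimated dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. For the mite response of B96, 78% of the 2-fold and 98% of the 4-fold changes were recovered among 22569 genes with 7 false calls. For the difference between the responses of B96 and B73, 56% and 86% were recovered. In the B75 experiment the figures were 74% and 99% for the response of B75 among 22572 genes, and 53% and 92% for the difference of responses. A simulated F1 placed at the linear mean of its parents gave 2458 genes off the log2 mid-parent in the B96 experiment, 99% of them higher, and 2035 in the B75 experiment, 98.7% of them higher.

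Alternatives were DESeq2 1.42.0, median-of-ratios size factors, no filter and a stricter filter of at least 1 CPM in 12 libraries (8 for the B73 libraries alone), a fit of the libraries compared alone, the replicate number as a block, infested in place of uninfested leaves for the line comparisons, genes with reads in both lines only, a linear mid-parent made by adding parental libraries, and leaving out each library in turn. Libraries thinned to one depth, and all alternatives of the results chosen after the data were seen, were added later. Chance was weighed by refitting other splits of the libraries compared, with 35 splits of 8 libraries, 60 draws for 12 or 16 libraries and 40 draws for 24, in which lines were regrouped within a treatment.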

Results

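The study measured leaf transcripts of maize after 24 hours of feeding by the spider mite Tetranychus urticae, a cell-content feeder with many host plants. B73 is the inbred line whose genome serves as the maize reference, and B96 and B75 are inbreds known for resistance to spider mites. Each experiment compared B73, one of the other inbreds and their F1, with and without mites, in 6 groups of 4 libraries. Control libraries held 12.5 to 20.9 M gene counts and infested libraries 9.98 to 16.6 M. The 10 most counted genes took a mean of 9.82% of the counts in control and 7.86% in infested leaves, but in B96 the means were 10% and 10.5%.

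Line and infestation were the main axes of variation in both experiments. The first principal component held 55.1% of the variance of log2 CPM in the B96 experiment and 52.3% in the B75 experiment and separated the lines, with the F1 between its parents. The second component held 22.4% and 24.8% and separated infested from control leaves.

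**Figure D1:**
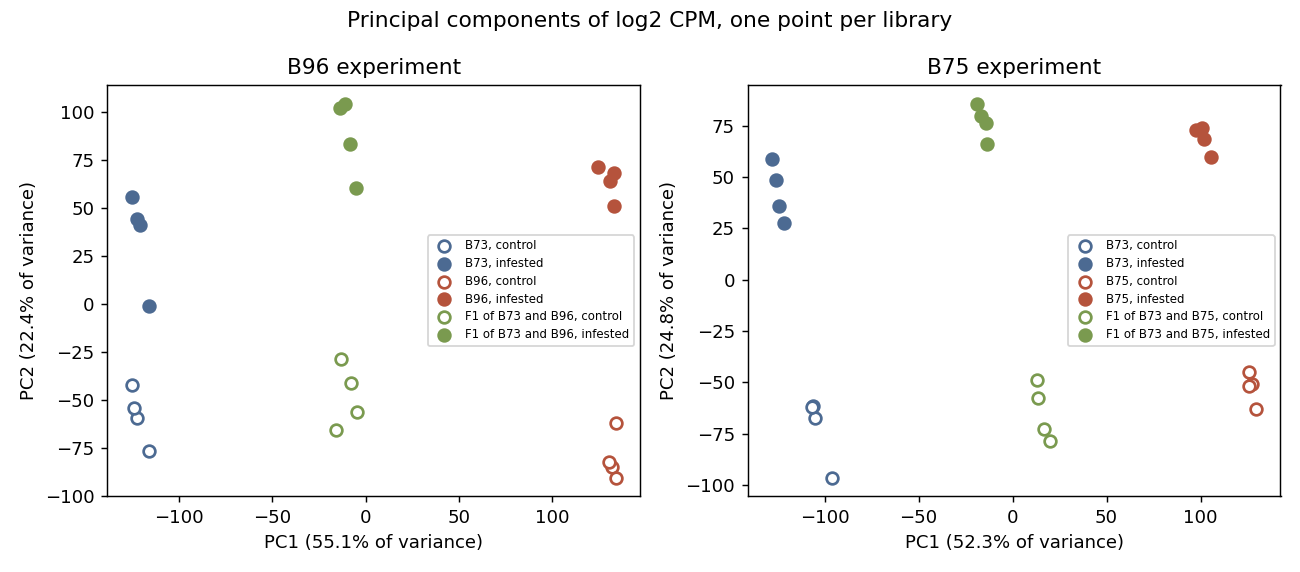
Principal components of log2 CPM, with PC1 on the x axis and PC2 on the y axis, 1 point per library, open for control and filled for infested leaves. PC1 (55.1% and 52.3% of variance) separates the lines and PC2 (22.4% and 24.8%) separates infested from control leaves.

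The response of B73 to mites addressed how a reference line reacts to feeding, and it was measured in 2 separate sets of plants. In the B96 experiment 5616 of 22569 genes changed, 3682 of them higher and 1934 lower in infested leaves (edgeR, adjusted p under 0.05), and 1784 rose and 188 fell at least 2-fold. Zm00001d010840 had 0 counts in the control libraries and 16.7 ± 9.19 CPM (n = 4) in infested ones, at least 406-fold higher, and Zm00001d011056 went from 0.0557 ± 0.0408 to 109 ± 44.3 CPM. Falls were smaller, with log2 fold changes of -2.09 ± 0.42 for Zm00001d013261 (196 ± 43.6 to 46.1 ± 19.6 CPM, adjusted p = 8.7e-04 by edgeR) and -1.98 ± 0.44 for Zm00001d053568. B73 plants of the B75 experiment changed 8692 genes, 4136 higher and 4556 lower, with 1966 rising and 1082 falling at least 2-fold. There Zm00001d048841 rose from 0.0142 ± 0.0284 to 35.9 ± 3.87 CPM and Zm00001d030670 from 0.0317 ± 0.037 to 55.6 ± 12.6 CPM, while Zm00001d047011 (log2 fold change -3.55 ± 0.61) and Zm00001d017766 (-2.85 ± 0.58) fell.

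The B73 responses of both experiments ran closely together. Of the 3627 and 4031 genes that rose in each, among 21539 tested in both, 2827 were the same, where 679 would overlap by chance, and 1613 fell in both, where 404 would. A single gene moved in opposite directions. The fold changes had a Pearson correlation of 0.876 and a Spearman correlation of 0.818 across genes, which are not independent replicates. The difference between both responses, tested directly with edgeR in the 16 B73 libraries, reached an adjusted p under 0.05 for 0 of 21017 genes. At an unadjusted p under 0.05 there were 692 genes, fewer than chance alone would give, and DESeq2 called 6. A count of 0 does not show that both responses were equal.

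A common core of genes responded in every line and F1. Among 21539 genes tested in both experiments, 1521 rose in all 6 mite responses and 789 fell in all 6, where 1.77 and 0.819 would be found if the 6 lists were independent. Of these, 795 rose and 34 fell at least 2-fold in every response. Zm00001d042540 rose by 8.87 to 11.34 and Zm00001d048841 by 7.70 to 10.54 on the log2 scale. Zm00001d011734 changed by -2.88 to -1.68 and Zm00001d013261 by -3.31 to -1.63. The number that fell in all 6 rested on B73 libraries of the B96 experiment, with 456 without control replicate 4, 453 without infested replicate 2 and 498 without infested replicate 4.

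The mite response of B96 was the widest in its experiment. In B96, 10781 genes changed, 5590 higher and 5191 lower, and 2763 rose and 1991 fell at least 2-fold. Zm00001d048660 rose from 0.0962 ± 0.146 to 355 ± 26.1 CPM and Zm00001d029359 from 0.0211 ± 0.0422 to 130 ± 20.5 CPM (log2 fold change 12.22 ± 0.67, adjusted p = 9.6e-12 by edgeR). Zm00001d027291 dropped from 7.84 ± 2.76 CPM to 0 counts, at least 141-fold lower, and Zm00001d011285 from 137 ± 62.7 to 0.627 ± 0.282 CPM. Of the genes that changed in B73, 2114 rose and 1133 fell in B96 too, and 236 moved in opposite directions.

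In B75, mites changed 8762 genes, 4900 higher and 3862 lower, close to the 8692 of B73 in the same experiment. Rises of at least 2-fold numbered 2482 and falls of that size 508. Zm00001d035683 rose from 0.0638 ± 0.0778 to 325 ± 90.9 CPM, and Zm00001d049407 from 0 counts to 27.4 ± 13.3 CPM, at least 568-fold higher. Falls on the log2 scale were -4.02 ± 0.78 for Zm00001d043610 and -3.8 ± 0.71 for Zm00001d011003 (adjusted p = 2.6e-04 and 1.8e-04 by edgeR). B75 shared 2583 rising and 2109 falling genes with B73, and 169 moved in opposite directions.

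**Figure D2:**
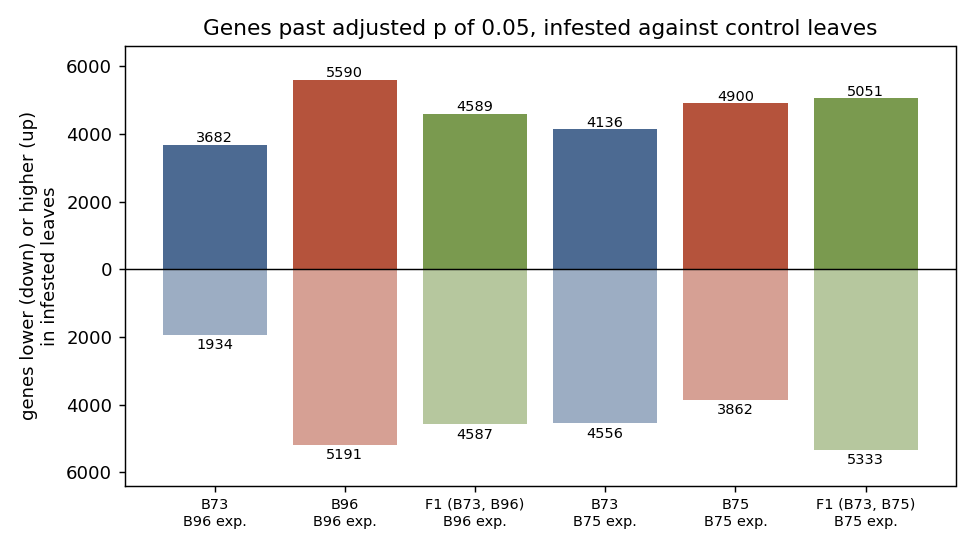
Number of genes that were higher (bars upward) or lower (bars downward) in infested than in control leaves at an adjusted p of 0.05 (edgeR), for each line and F1 on the x axis. B96 had 5590 higher and 5191 lower genes, against 3682 and 1934 in B73 of the same experiment.

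The F1 plants responded strongly as well. The F1 of B73 and B96 changed 9176 genes, 4589 higher and 4587 lower, and the F1 of B73 and B75 changed 10384, 5051 higher and 5333 lower. In the B96 experiment Zm00001d010840 rose in the F1 from 0 counts to 47 ± 30.6 CPM, at least 1020-fold higher, and Zm00001d011056 rose by 11.92 ± 0.72 on the log2 scale. Zm00001d039049 fell from 26.4 ± 8.36 to 1.82 ± 0.555 CPM, and ENSRNA049479033 fell from 14.1 ± 14.9 to 0.366 ± 0.193 CPM with an adjusted p of 4.8e-02 (edgeR) that was lost in 7 of 15 alternative fits. In the B75 experiment Zm00001d011056 rose by 12.25 ± 0.71 and Zm00001d038703 by 11.88 ± 0.61, while Zm00001d017766 (-3.97 ± 0.63) and Zm00001d051099 (-3.55 ± 0.5) fell. Between the F1s of both crosses, 3599 genes rose in both and 3511 fell in both, and 14 moved in opposite directions.

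The genes that mites induced in B73 formed a set that moved together in every genotype. In the B96 experiment the 1863 set members, taken from B73 of the other experiment, had a median log2 fold change of 1.63 in B73 with 1546 rising and 1 falling, of 1.73 in B96 with 1334 rising and 26 falling, and of 1.91 in the F1 with 1621 rising and 2 falling. Camera with Benjamini-Hochberg adjustment gave 5.38e-130, 3.15e-45 and 1.32e-107, and the calls held with an estimated correlation (adjusted p = 0.00101, 0.0305 and 0.00148). The 1729 members in the B75 experiment had medians of 1.77 in B73, 1.72 in B75 and 1.96 in the F1, with 1538, 1301 and 1531 rising and 0, 8 and 2 falling, and all 3 calls held with an estimated correlation (adjusted p = 1.42e-04, 0.00139 and 2.6e-04). Mean set scores in infested leaves were 1.78 ± 0.39 in B73, 1.69 ± 0.08 in B96 and 2.20 ± 0.29 in their F1, and 2.01 ± 0.22 in B73, 1.37 ± 0.13 in B75 and 2.03 ± 0.16 in their F1 (SD, n = 4). Uninfested B75 had a mean score of -0.49 ± 0.07, so from control to infested leaves scores rose by 1.86 in B75 and by 2.01 in B73 of that experiment. The weakest B73 score, 1.244, belonged to infested replicate 1 of the B96 experiment. The infested libraries lay above the control libraries of their genotype in each of the 6 cases, with an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and 0.0534 after adjustment over 28 comparisons.

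The mite-repressed set fell less evenly. In the B96 experiment its 1039 members had median log2 fold changes of -0.66 in B73, where 355 fell and 0 rose, of -1.26 in B96, where 748 fell and 10 rose, and of -1.22 in the F1, where 831 fell and 0 rose. Camera called all 3 (adjusted p = 4.21e-27, 5.76e-27 and 1.15e-38), but none of the calls held with an estimated correlation (adjusted p = 0.184, 0.184 and 0.131). Fry called all 3 (adjusted p = 0.00522, 4.52e-05 and 4.52e-05), but it does not weigh the set against other genes. In the B75 experiment the 181 members had medians of -1.33 in B73 with 145 falling, -0.78 in B75 with 97 falling and -1.36 in the F1 with 143 falling, and these calls held (adjusted p = 8.9e-04, 0.0129 and 0.00137 with an estimated correlation).

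**Figure D3:**
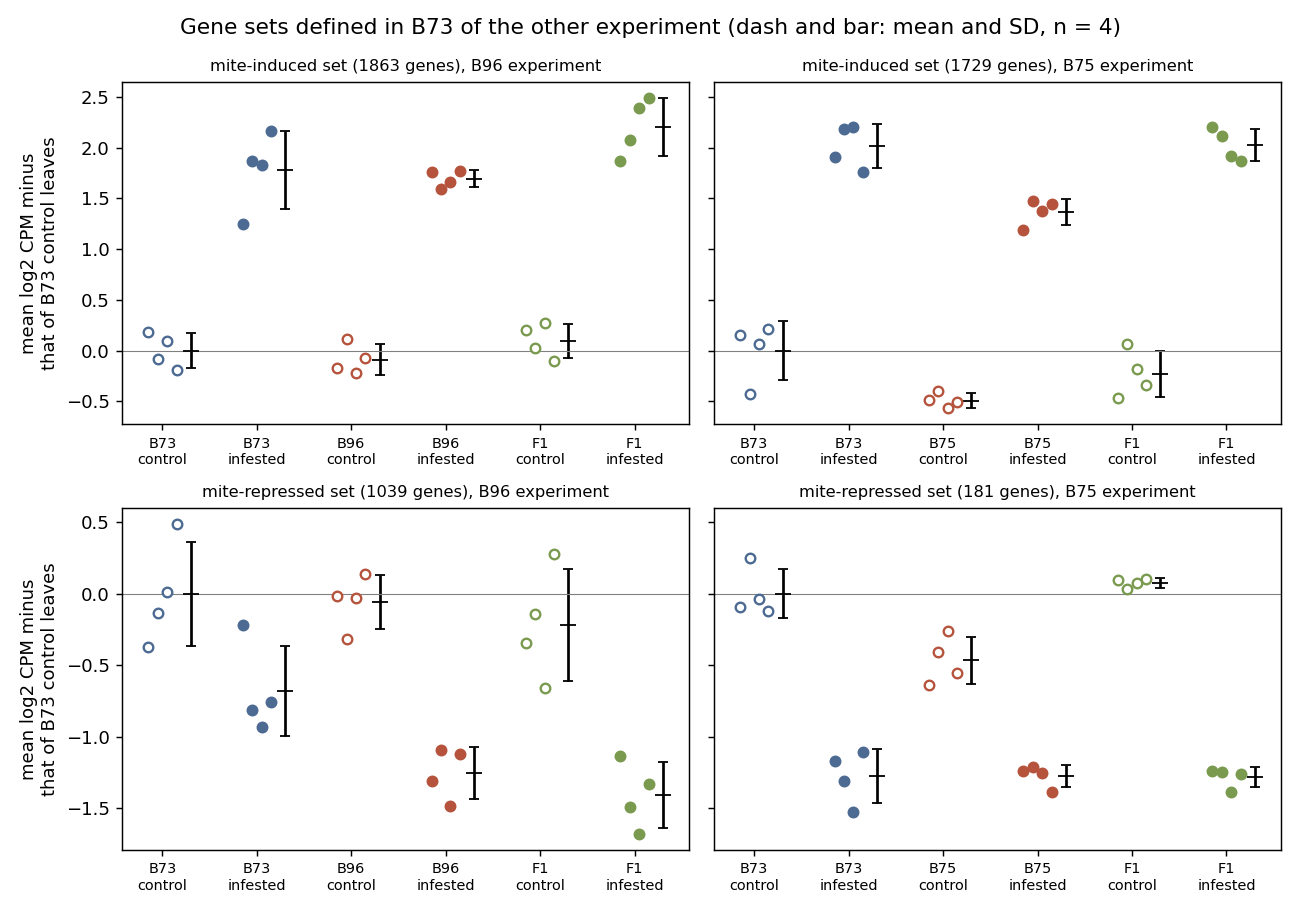
Mean log2 CPM of the members of each set relative to the B73 control mean (y axis), 1 point per library, with the mean and SD of each group as black bars beside the points. Infested means of the induced set are 1.78 in B73, 1.69 in B96 and 2.20 in their F1, and 2.01, 1.37 and 2.03 in the B75 experiment. The uninfested mean of this set in B75 is -0.49.

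In uninfested leaves the inbreds differed from B73 at more genes than mites changed in any of them. B96 and B73 control leaves differed at 14531 of 22569 genes, 7274 higher and 7257 lower in B96, and B75 and B73 at 12331 of 22572, 5707 higher and 6624 lower in B75. Zm00001d031241 (98.4 ± 19.2 CPM) and Zm00001d017233 (57.1 ± 5.40 CPM) were read in B96 and had 0 counts in B73, at least 2390-fold and 1390-fold higher, whereas Zm00001d043982 (131 ± 6.76 CPM in B73) and Zm00001d013857 (80.3 ± 27.6 CPM) had 0 counts in B96, at least 2320-fold and 1420-fold lower. In B75, Zm00001d011013 and Zm00001d035217 were at least 1640-fold and 1000-fold higher than in B73, and Zm00001d052011 and Zm00001d023759 at least 1230-fold and 1050-fold lower. The differences of B96 and of B75 from B73, each against its own B73 libraries, shared 2643 higher and 3708 lower genes, and 1689 went opposite ways. Both lists compare with B73, so a gene peculiar to B73 enters both and no chance value is given. The induced set did not stand apart from other genes in uninfested B96 (median -0.12, camera adjusted p = 0.982). In uninfested B75 the median was -0.59, with 278 members higher and 708 lower. Camera missed the threshold there (adjusted p = 0.0672, or 0.718 with an estimated correlation). Fry, which does not weigh the set against other genes, passed it (adjusted p = 0.0126).

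Some genes were read in only 1 parent. In the B96 experiment 154 genes with a mean of at least 5 CPM in B73 had under 3 counts over the 8 B96 libraries, and 162 had reads in B96 and under 3 counts over the 8 B73 libraries. The corresponding numbers for B75 were 123 and 164. In uninfested F1 leaves such genes stood at a median of 0.469 and 0.414 of the level of the parent that read them in the B96 cross, and at 0.515 and 0.436 in the B75 cross. The share with an F1 level between 0.25 and 0.75 of that parent was 94.8% for genes read in B73 and 73.5% for genes read in B96, and 94.3% and 93.3% in the B75 cross.

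**Figure D4:**
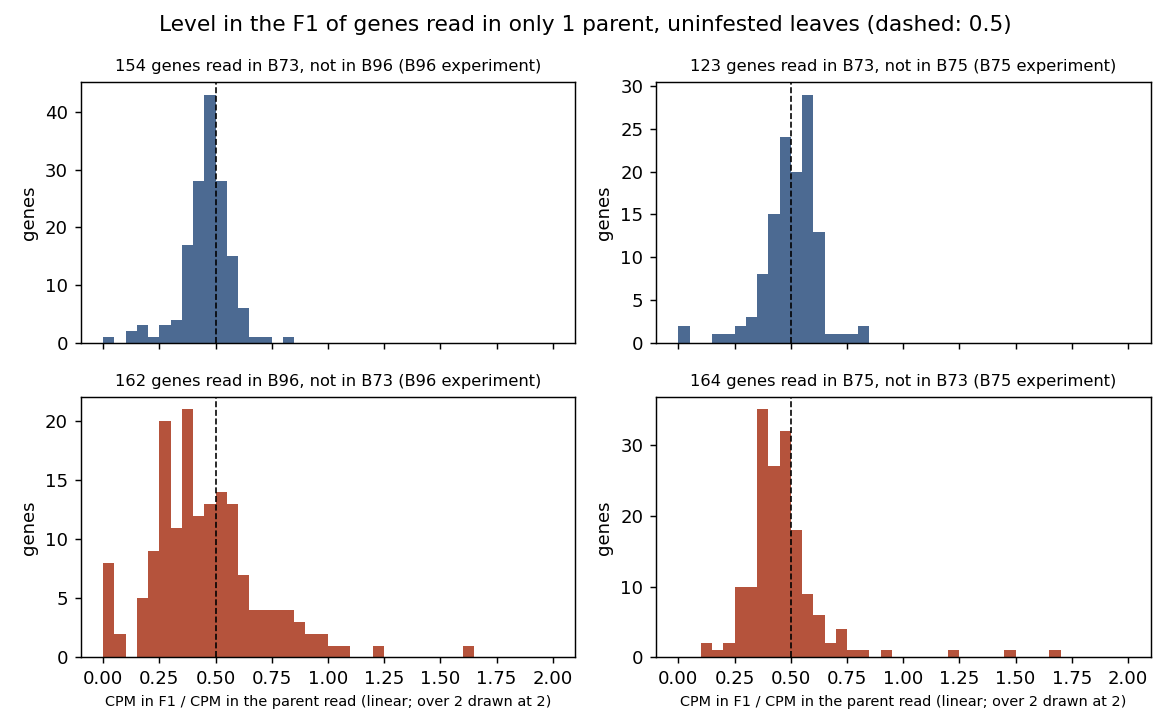
Level in the uninfested F1 divided by that in the parent that reads the gene, for genes with under 3 counts over the 8 libraries of the other parent, by cross and expressing parent. Medians are 0.469 and 0.414 in the B96 cross and 0.515 and 0.436 in the B75 cross.

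Whether B96 reacts to mites differently from B73 was tested as a difference of responses. It passed the threshold at 4975 genes, 2355 with a higher and 2620 with a lower fold change in B96. Among them, 1642 rose and 1565 fell in B96 and were not called in B73, 583 rose and 166 fell in B73 and were not called in B96, 380 rose in both and more in B96 and 60 less, 180 fell in both and more in B96 and 3 less, and 88 rose and 148 fell in B96 while moving the other way in B73. Zm00001d048660 rose to 355 ± 26.1 CPM in infested B96 but to 7.85 ± 5.85 CPM in infested B73, a difference of 8.69 ± 1.08 on the log2 scale, and Zm00001d053918 reached 7.82 ± 2.41 CPM in infested B96 against 0.173 ± 0.136 CPM in infested B73. Zm00001d018738 went from 0.846 ± 0.649 to 23.6 ± 11.1 CPM in B73 and from 0.947 ± 0.307 to 0.182 ± 0.140 CPM in B96 (-7.01 ± 1.00, adjusted p = 6.8e-05 by edgeR). Zm00001d027291 (-13.78 ± 2.30, a fitted value that rests on 0 counts in infested B96 and is no bound) lost its reads in infested B96 and had 29 counts in infested B73, most of them in replicate 1, without which its call was lost (edgeR adjusted p = 0.165). The repressed set had a median difference of -0.59, with 27 members higher and 199 lower (camera adjusted p = 4.6e-07, but 0.659 with an estimated correlation), and the induced set one of 0.09 (camera adjusted p = 0.336).

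The response of B75 differed from that of B73 at 2077 genes, 1475 with a higher and 602 with a lower fold change in B75. DESeq2 gave 1602 higher and 1087 lower, and without B75 control replicate 4 the count was 1271. Of the 2077, 679 rose and 187 fell in B75 and were not called in B73, 263 rose and 362 fell in B73 and were not called in B75, 274 rose in both and more in B75 and 73 less, 20 fell in both and more in B75 and 13 less, and 125 rose and 44 fell in B75 while moving the other way in B73. Zm00001d014840 reached 20.3 ± 16 CPM in infested B75 against 0.422 ± 0.280 CPM in infested B73, a call lost without B73 control replicate 5 (edgeR adjusted p = 0.075). Zm00001d002564 was nearly unread in uninfested B75 (0.0319 ± 0.0389 CPM) and rose there to 34.7 ± 3.37 CPM, while B73 went from 2.69 ± 2.27 to 25.9 ± 7.19 CPM (difference 6.52 ± 1.08, adjusted p = 5.1e-04 by edgeR). Zm00001d012229 went from 0 counts to 0.332 ± 0.189 CPM in B73 and from 5.82 ± 1.38 to 4.72 ± 1.03 CPM in B75. ENSRNA049479040 (-8.57 ± 2.60) varied from 0.358 to 104 CPM among the B75 control libraries and lost its call in 13 of 22 alternative fits. The repressed set had a median difference of 0.40, with 21 members higher and 4 lower (camera adjusted p = 0.00212, but 0.311 with an estimated correlation). Mean scores of this set were -1.27 in infested B75 and -1.28 in infested B73. In uninfested leaves B75 stood at -0.47 relative to B73 (exact permutation p = 0.0286, and 0.0534 after adjustment). The smaller fall of the set in B75 thus went with a lower uninfested level. The differences of both lines from B73 shared 430 genes in the higher and 148 in the lower direction, and 151 went opposite ways, in lists that again share B73.

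The F1s addressed how the response is inherited. The response of the F1 of B73 and B96 differed from that of B73 at 34 genes, 21 higher and 13 lower, and from that of B96 at 2023. DESeq2 called 162 in the comparison with B73, 119 higher and 43 lower, and a fit with no low-count filter 57. The replicate number as a block raised the count of 34 as well, as given in the closing section. The count of 34 became 21 without B73 control replicate 2, 20 and 54 without F1 control replicates 2 and 4, and 56 and 19 without F1 infested replicates 1 and 3, and the count of 2023 became 1221 without B96 control replicate 3 and 1320 without B96 infested replicate 1. Along the 4975 genes whose response differed between the parents, 80.8% of F1 responses lay closer to that of B73, and the F1 stood at -0.36 on a scale from -1 at B73 to 1 at B96 (-0.42 to -0.27 when leaving out each library). The position was taken on log2 CPM, where an F1 at the linear mean leans to the parent with the higher uninfested level. Reads of the B96 copy lost on the B73 genome would also move the F1 towards B73. Neither was tested for this position. In uninfested leaves the F1 of B73 and B96 stood at -0.14 over 14531 genes, and that of B73 and B75 at 0.02 over 12331. The response of the F1 of B73 and B75 differed from that of B73 at 198 genes and from that of B75 at 556, 143 higher and 413 lower, and the F1 stood at -0.07 (-0.11 to -0.03) over 2077 genes. DESeq2 called 419 against B73, and 1182 against B75, 584 higher and 598 lower, and median-of-ratios size factors gave 177 higher and 299 lower against B75. Leaving out B73 control replicate 5 gave 128 against B73. Against B75 the count ranged from 201 without B75 infested replicate 1 to 1360 (729 higher and 631 lower) without B75 control replicate 3, and lay at 244 to 333 without B75 control replicate 1 (315) or 4 (244), B75 infested replicate 2 (264), F1 control replicate 2 (333) or F1 infested replicate 2 (329), 3 (252) or 4 (260).

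The response of each F1 was also tested against the mean of its parents' responses on the log2 scale. In the B96 cross 71 of 22569 genes departed from it, 50 higher and 21 lower, and in the B75 cross 22 of 22572, 14 higher and 8 lower. Zm00001d021167 rose in the F1 of B73 and B96 from 0.454 ± 0.251 to 17 ± 6.73 CPM, like B73 (3.46 ± 2.42 to 27.7 ± 8.63 CPM), and stood at 0.0523 ± 0.0625 CPM in infested B96 (F1 minus mid-parent 4.92 ± 0.84). Zm00001d037689 went from 0.453 ± 0.492 to 66.9 ± 7.11 CPM in B96, from 57 ± 6.13 to 48.4 ± 7.54 CPM in B73 and from 19.3 ± 4.09 to 43.5 ± 8.14 CPM in the F1 (-2.25 ± 0.29, adjusted p = 7.2e-04 by edgeR). The calls of Zm00001d002564 (4.49 ± 0.98) and Zm00001d039301 (-2.57 ± 0.55) were lost in 21 and 20 of 30 alternative fits. In the B75 cross Zm00001d031934 rose to 1530 ± 256 CPM in the F1, beside 1560 ± 107 CPM in B73 and 49.6 ± 26.9 CPM in B75, from 5.31 ± 2.71, 146 ± 74.3 and 0.884 ± 1.11 CPM (3.48 ± 0.62), and Zm00001d024281 had a difference of 2.85 ± 0.54 that was lost in 9 of 30 alternative fits. Without B75 control replicate 1 or F1 control replicate 1 the call of Zm00001d031934 was lost (edgeR adjusted p = 0.152 and 0.058). Zm00001d018384 (-2.67 ± 0.29) and Zm00001d006525 (-2.55 ± 0.39) lay below the mid-parent response on the log2 scale. Zm00001d006525 went from 6.82 ± 0.532 to 5.43 ± 0.619 CPM in the F1, from 13.7 ± 1.86 to 9.92 ± 1.4 CPM in B75 and from 0 counts to 0.256 ± 0.123 CPM in B73, so its value rests on 0 counts and is no bound, and it was not called without B73 infested replicate 7 (edgeR adjusted p = 0.0588) or in thinned libraries (0.0855). No linear mid-parent was tested for the responses. A departure on the log2 scale can come from the scale alone where parents start at unlike levels, as they did for Zm00001d037689 and Zm00001d006525. DESeq2 called 247 genes in the B96 cross and 171 in the B75 cross. The replicate number as a block also raised the counts of 71 and 22, as given in the closing section. The 71 became 45 without B96 control replicate 2, 36, 38 and 47 without F1 control replicates 1, 2 and 3, and 47 and 42 without F1 infested replicates 2 and 3, and the 22 became 55 without B73 control replicate 6 and 14 without F1 control replicate 1.

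In uninfested leaves the F1s lay off the log2 mid-parent more often above than below it. In the B96 cross 7578 genes departed from it, 5314 higher and 2264 lower, and in the B75 cross 4474, 3573 higher and 901 lower. DESeq2 gave 4631 higher and 3129 lower in the B96 cross and 3272 higher and 1665 lower in the B75 cross, and the median of all genes was 0.106 and 0.067. Against a mid-parent on the linear scale the counts fell to 2646 (1146 higher and 1500 lower) and 465 (244 higher and 221 lower), and the fit of the B75 cross to the control libraries alone gave 2935. Zm00001d034208 had 5.79 ± 1.26 CPM in the F1 of B73 and B96 against 0 counts in B73 and 0.0952 ± 0.0976 CPM in B96, and Zm00001d028617 had 6.03 ± 1.51 CPM in the F1 of B73 and B75 against 0 counts and 0.143 ± 0.086 CPM, so both stood above either parent. Zm00001d003140 (65.1 ± 39.5 CPM in the F1, 40.8 ± 9.11 CPM in B96, 0 counts in B73) and Zm00001d046604 (140 ± 63.3 CPM in the F1, 144 ± 55 CPM in B75, 0.0352 ± 0.0704 CPM in B73) stood near the parent that reads them, and Zm00001d046604 was not called against a linear mid-parent. Zm00001d018763 and Zm00001d018761 had 20.8 ± 4.97 and 10.6 ± 2.63 CPM in B96 and 0 counts in the F1. The call of Zm00001d018763 was lost without B73 control replicate 1 (edgeR adjusted p = 0.0525) or 3 (0.0549), and that of Zm00001d018761 in libraries thinned to one depth. In the B75 cross Zm00001d028432 (-3.19 ± 0.69) and Zm00001d011285 (-3.15 ± 1.06) lay below the mid-parent, the former not called against a linear mid-parent (edgeR adjusted p = 0.0501) and the latter with B73 control libraries between 2.18 and 654 CPM and a call lost in 10 of 20 alternative fits.

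MicroRNA precursors were the only features the table names, and they were low. Among uninfested leaves MIR168a, a precursor of the microRNA that targets ARGONAUTE1, had 5.77 ± 3.72 CPM in B73, 0.0192 ± 0.0383 CPM (1 count) in B96 and 1.39 ± 1.80 CPM in their F1, and the B96 level was lower than that of B73 (log2 fold change -7.71 ± 1.24, adjusted p = 1.1e-05 by edgeR). MIR168b was higher in B96, with 1.36 ± 0.481 against 0.351 ± 0.173 CPM (1.95 ± 0.51, adjusted p = 2.1e-03), and MIR156d was lower (-2.06 ± 0.51, adjusted p = 1.2e-03). With mites MIR156j rose in B96 from 0.243 ± 0.121 to 0.929 ± 0.183 CPM (1.91 ± 0.58, adjusted p = 9.2e-03). In uninfested leaves its level in the F1 of B73 and B96 lay below the mid-parent (-2.65 ± 0.78, adjusted p = 1.2e-02 by edgeR). That value rests on 3 counts in the F1 (0.0469 ± 0.0318 CPM), 13 in B96 and 32 in B73, of which 18 came from 1 library. In the B75 experiment MIR156d fell with mites in B73 from 1.26 ± 0.479 to 0.508 ± 0.154 CPM (-1.28 ± 0.38, adjusted p = 1.1e-02), and MIR168a fell from 6.23 ± 1.67 to 4.09 ± 0.565 CPM (-0.60 ± 0.23, adjusted p = 4.2e-02), a call that was lost in 10 of 15 alternative fits. Libraries selected for poly(A) RNA count precursor transcripts, not mature microRNAs. Other tested contrasts of these 4 precursors for a mite response or between inbreds missed the threshold, and MIR156j and MIR168b were too low to be tested in the B75 experiment.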

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

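Tests of gene sets, of each F1 response against that of a parent with its other splits, of thinned libraries, of genes read in both lines, of the ratio with B73 of the other experiment and of the MIR168a ratio in infested leaves and without replicate 4 were chosen after the result was seen. Libraries far from the rest of their group were found in 18 of 192 groups of 4, and chance gives about 1 in 20 groups. The differences between groups listed here each passed a direct test of the difference, for genes in edgeR and for the repressed set in camera at its preset correlation, a call that an estimated correlation ended in both experiments.

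Mites changed 1.92 times as many genes in B96 (10781) as in B73 of the same experiment (5616), and the responses differed at 4975 genes. The tests argue against library depth, since the ratio was 1.96 with libraries thinned to one depth. Without the weak B73 infested replicate 1 the ratio was 1.79, and the B73 count rose to 6103. B73 then had fewer libraries than B96, which by itself lowers its count, so this ratio does not decide on that library. With genes read in both lines alone the ratio was 1.9, which argues against genes read in one line adding to its count, whereas their share of the differing genes (0.0201%) decides nothing, since a gene without reads in one line can hardly pass that test. Against B73 of the B75 experiment, which changed 8692 genes in the fit of that experiment, the ratio was 1.24. The size of the excess thus depends on which B73 plants and which fit are compared, and these 2 were not told apart. A difference between the lines may remain, and what in the lines brings it about was not tested.

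The F1s lay above the log2 mid-parent more often than below it in uninfested leaves, at 70.1% of the 7578 called genes in the B96 cross and 79.9% of 4474 in the B75 cross. A linear mid-parent gave 43.3% of 2646 and 52.5% of 465 genes, so the log scale of the mid-parent may account for the excess. Thinned libraries still gave 69.9% in the B96 cross, which argues against library depth. Expression near the sum of both parental alleles would give the same picture and was not tested by allele, and no other biological explanation was tested.

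MIR168a was nearly unread in uninfested B96 and MIR168b was higher there than in B73. Reads of one precursor counted on the other would keep the sum alike, if none were lost as not unique. The sum was 4.43 times as high in B73, which argues against a plain exchange of reads as the whole account. MIR168b rose only from 0.351 CPM in B73 to 1.36 CPM in B96, beside 5.77 CPM of MIR168a in B73. The sum therefore does not decide where the added MIR168b reads came from. A B96 copy that is silent or not readable on the B73 genome would leave the F1 near the middle, and the F1 level was 0.241 of that of B73 in uninfested leaves, just under the range set for it, and 0.344 in infested leaves, inside it, so the explanation cannot be told apart from others. Replicate 4 was the highest library in each B73 and F1 group of this experiment, with 11.2 CPM in uninfested B73, 9.6 in infested B73 (1.66 to 2.62 in the others), 4.08 in the uninfested F1 (0.361 to 0.603) and 3.32 in the infested F1 (0.538 to 0.914), and MIR168b stood at 2.25 CPM in that uninfested F1 library (0.842 to 1.03). Without replicate 4 of both groups the ratio was 0.124 in uninfested and 0.341 in infested leaves, so it depends on that replicate in uninfested leaves.

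Among libraries, infested B73 replicate 1 of the B96 experiment had 14.4 M gene counts (11.2 to 11.6 in the others), and uninfested replicate 3 of the F1 of B73 and B96 had 14.4 M (16.1 to 16.3). The 10 most counted genes held 10.5% in B96 control replicate 4 (9.85 to 9.93). The mite-repressed set score was -1.39 in infested replicate 3 of the F1 of B73 and B75 (-1.26 to -1.24).

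Among genes of the B96 experiment, infested B73 replicate 1 had 1.93 CPM of Zm00001d027291 (0 to 0.0783) and 52.1 CPM of Zm00001d039301 (131 to 139), and infested B73 replicate 4 had 1.26 CPM of MIR156d (0.621 to 0.705). In the F1, uninfested replicate 4 had 124 CPM of Zm00001d003140 (40.3 to 49.1) and infested replicate 3 had 19.8 CPM of Zm00001d002564 (9.49 to 11). In the B75 experiment, MIR168a stood at 6.11 CPM in infested B75 replicate 3 (3.22 to 3.46), Zm00001d011285 at 7.13 CPM in uninfested F1 replicate 4 (1.86 to 2.71) and Zm00001d031934 at 2.53 CPM in uninfested B75 replicate 1 (0.194 to 0.571). ENSRNA049479040 stood at 1.13 CPM in uninfested B73 replicate 7 (0.14 to 0.228) and at 14.6 CPM in infested B75 replicate 1 (0.125 to 0.56).

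The responses of B96 and B73 differed by 8.69 (Zm00001d048660), 8.59 (Zm00001d053918), -13.78 (Zm00001d027291) and -7.01 (Zm00001d018738) on the log2 scale, and the repressed set by a median of -0.59 (adjusted p = 0.659 with an estimated correlation and 0.159 with fry). Those of B75 and B73 differed at 2077 genes, by 6.99 for Zm00001d014840, 6.52 for Zm00001d002564, -8.57 for ENSRNA049479040 and -5.59 for Zm00001d012229, and by a median of 0.4 for the repressed set (adjusted p = 0.311 with an estimated correlation and 0.00826 with fry). The values of Zm00001d053918, Zm00001d027291 and Zm00001d012229 are fitted ones that rest on a group with 0 counts and are no bounds. The F1 response differed from that of B73 at 34 and of B96 at 2023 genes in the B96 cross, and from that of B73 at 198 and of B75 at 556 genes in the B75 cross.

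Other splits of the libraries, fitted alone, were used to weigh chance. For the mite responses and line differences 1 of 35 splits, the real one, gave as many genes. This is the smallest share that 35 splits can give, without adjustment for the number of comparisons, so it argues against chance only to that extent. The real counts and highest others were 5026 and 0 in B73, 10634 and 1 in B96, 6593 and 0 in the F1 and 13945 and 0 between uninfested B96 and B73, and 7170 and 1, 8339 and 1, 9479 and 0, and 10261 and 0 for the same comparisons with B75. The splits leave chance undecided where more than 2 groups entered a comparison, since lines differ there even with no effect of the kind tested and so are not interchangeable. This holds for the F1 against the mid-parent, with 2 of 60 splits as large (7286, highest other 12786) in the B96 cross and 1 of 60 (2935, highest other 0) in the B75 cross, and for the F1 response against the mid-parent response, with 1 of 40 (71, highest other 0) and 2 of 40 (22, highest other 2811). It holds for the F1 response against B73 and B96, with 2 of 60 each (24 and 1689, highest others 3875 and 6043), and against B73 and B75, with 4 of 60 each (152 and 501, highest others 4412 and 5745). It holds for the difference of responses of B96 and B73 (3 of 60, 5551, highest other 15731) and of B75 and B73 (4 of 60, 1514, highest other 8501). Among differences of responses, each other split as large as the real one put a difference between lines into the contrast, which points to a structure of the samples. Splits in which the lines cancelled gave at most 0 genes, with 27 such splits for B96 against B73 and 16 for B75 against B73. The F1 response had 26 against B73 and 26 against B96, and 22 against B73 and 19 against B75, also with at most 0. Their groups mix lines, which widens the spread within groups, so these splits do not exclude chance either.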

How the results depend on the processing

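Tests on thinned libraries, of gene sets, of the F1 response against each parent and of genes shared by all 6 responses were chosen after the result was seen. No called gene or gene set reversed. With a linear mid-parent the higher share of genes in the B96 cross turned from 70.1% to 43.3%, and without B75 control replicate 3 that of the F1 response against B75 turned from 25.7% to 53.6%. Higher shares that began between 45.3 and 50.1% also crossed the middle under some settings. Of 144 counts of genes under other settings 131 stayed within 1.5 times the first count, as did 315 of 344 counts without 1 library. Of 649 values of single genes under other settings 18 lost and 3 gained a call, and of 1208 without 1 library 83 lost and 4 gained one. Of 140 values of gene sets 15 lost and 6 gained a call.

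The cause was not tested for the counts that moved, except that counts lower without 1 library come from fits with fewer samples. DESeq2 gave 247 (B96 cross) and 171 (B75 cross) genes for the F1 response against the mid-parent response, 162 and 419 against that of B73, and 1182 against that of B75. For the B73 response between experiments edgeR called 0 genes, with 692 at an unadjusted p under 0.05, and DESeq2 called 6. A linear mid-parent gave 2646 and 465 genes for the uninfested F1. The fit of the libraries compared alone gave 2935 in the B75 cross, and no low-count filter gave 57 for the F1 response against B73 in the B96 cross.

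The replicate number as a block gave 117 and 37 genes for the F1 response against the mid-parent response and 65 for that against B73 in the B96 cross. The labels name a randomized block design but do not say that the number marks a block, although each number of an experiment covers a run of 6 library numbers. Libraries of one number had a mean correlation of 0.108 (-0.179 to 0.497) in the B96 and 0.116 (-0.271 to 0.47) in the B75 experiment after removal of group means, against -0.0349 and -0.039 for other numbers. Of 24 libraries 16 and 17, and not all, correlated best with their own number. This is a hint from the data, not the design, that libraries of one number share variation. The main fits and the exact permutation tests leave the number out, so their p-values do not account for such sharing.

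Leaving out 1 library gave 36 to 82 genes (B96 cross) and 14 to 55 (B75 cross) for the F1 response against the mid-parent response, 19 to 56 and 128 to 271 against B73, 1221 to 2248 against B96 and 201 to 1360 against B75. The difference of responses of B75 and B73 ranged from 1271 to 2377, and genes lower in all 6 responses from 453 to 921. Mite responses of single genotypes stayed within 1.5 times, from 4122 to 6103 in B73 of the B96 experiment. Depth limits genes of few counts, since infested libraries held a median of 12.4 M gene counts against 16.4 M in control.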

Other observations

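The tests of identifier order and of genes nearly unread in the F1 were thought of after the data were seen, with what each would show written before it was run, and the tests of other splits for the B73 responses between experiments and of the order of differing responses were chosen after the result was seen.

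Some genes that only B96 read were nearly absent from the F1. Of 162 genes read in B96 and not in B73, 10 stood under 0.1 of the B96 level in the uninfested F1, against 1 of 154 genes read in B73 only (Fisher exact p = 0.0107 across genes, which are not independent replicates). In the B75 cross the numbers were 0 of 164 and 2 of 123 (Fisher exact p = 0.183). Chance low counts in the 4 uninfested F1 libraries are argued against, since 8 of the 10 genes also stood under 0.1 of the B96 level in infested leaves, with a median of 0.0412 and a highest value of 0.165. Zm00001d029125, for example, had 26 and 32.8 CPM in uninfested and infested B96 and 0.605 and 0.773 CPM in the F1. Repression of the B96 copy in the F1, or a B96 parent of the cross that differed from the B96 plants sampled, may be the reason, and neither was tested.

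Zm00001d037913, singled out after its values were seen, was read in B73 and not in B96 or B75. Its uninfested F1 level was 0.0445 of that of B73 in the B96 cross and 0.044 in the B75 cross, and its infested level 0.478 and 0.455. The uninfested ratios rest on 2 and 4 counts over the F1 libraries, against 0.716 and 1.44 CPM in uninfested B73.

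A hypothesis that line differences follow shared stretches of the genome was tested by the order of identifier numbers, in windows of 100 genes against 1000 random orders. Between uninfested B75 and B73 the variance over windows was 1.69 times that of random orders, and 0 of the 1000 were as large, as shared stretches would give. The windows there ranged from 36 to 70%. The extremes over all random orders together were 33 to 79%, a range too wide to tell whether a single stretch stood out. Between B96 and B73 the ratio was 1.16, within the random orders, but only 39 of 1000 were as large, so that bound does not exclude the hypothesis. The mite responses, with 1.18 (39) in B96 and 1.15 (55) in B75, and the differences of responses, with 1.23 (5) in B96 and 1.18 (31) in B75, leave it open too. Identifier numbers stand in for positions here, which were not available.

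For the B73 responses between experiments edgeR called 0 genes (692 at an unadjusted p under 0.05, DESeq2 6) and the highest other split 13. All 60 of 60 splits give at least 0 genes by construction, so the splits say nothing on chance here.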
